A study of Mus musculus with 3 samples.

How the data were processed

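ETV5 and H3K4me3 were each measured by chromatin immunoprecipitation and sequencing in 1 library from mouse AT2 cells, and 1 input library is listed beside them. Samples were grouped by the antibody named in their labels. Peaks were called per library with MACS2 version 2.1.0.20150420, per the submitters' processing notes and per the file headers, with a q-value threshold of 0.05, at most 1 tag kept per position and an effective genome size of 1.87e+09. The aligner is not given in the sources used here. The pileup signal of each peak is, per the file headers, the number of overlapping fragments at the summit, with the larger of ChIP and input scaled down to the smaller. In both comparisons the input was the larger, so the ChIP pileups are unscaled fragment counts, and all of them were whole numbers. The fold enrichment ratio of each peak is the authors' deposited value. It is the pileup over the local background of the input, with 1 added to both. The −log10 p-value and −log10 q-value of each peak are also as the authors deposited them. Width and summit position came from the same files.

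Per the file headers the ETV5 list was made from 5715049 tags of 75 bp against 27495486 input tags with a fragment length of 203 bp, and the H3K4me3 list from 34907608 tags of 50 bp against 44758677 input tags with a fragment length of 288 bp. Per the file headers the input used for ETV5 also carries another name than the input sample described in the labels, while that used for H3K4me3 matches it. The lists therefore differ in depth, tag length and background, and the lower ETV5 depth limits which weak peaks could be called. A pileup of 13, the ETV5 median, carries a Poisson counting error that is large beside that of an H3K4me3 pileup of 185.

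The labels name build mm9, and the coordinates are those of GRCm38. ETV5 peaks on Y reach 90.8 Mb, close to the last Y gene of the GRCm38 gene table, and 66.0% of H3K4me3 summits lie within 1 kb of a gene boundary of that table, against a mean of 3.20% and a maximum of 3.66% over 100 circular shifts. Positions are therefore given as GRCm38, as in the files. Genes came from the GRCm38.p6 RefSeq gene table (21883 protein-coding genes among 49939). Strand and genome sequence were not used here. The planned distance to start sites was replaced by the distance to the nearer end of a gene (gene boundary), and the planned search for ETS motifs was not run.

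Peaks on assembled chromosomes were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with a minimum overlap of 1 bp, and both overlap counts were checked with bedtools 2.31.1. For the alternative of at least 50% of an ETV5 peak, bases were summed over H3K4me3 peaks (14403 peaks, also with bedtools coverage), and 14299 reached it within a single H3K4me3 peak. Chance overlap came from 1000 seeded circular shifts of the ETV5 peaks within the span of peaks on each chromosome. Alternative settings used 100 placements each. Shifts were of at least 1 Mb, a limit set after the data were seen, when a shift close to 0 on a chromosome was found to leave its peaks almost in place. Figures were drawn with matplotlib 3.10.9. A gene counted as marked when any base of an H3K4me3 peak lay within 1 kb of a boundary, and as having ETV5 when a summit lay within 5 kb of one. Each of 18 gene lists was compared with 10000 random lists with as many marked and unmarked genes, and the percentile is the share of random lists with a lower count with ties divided evenly. Because there is 1 library per antibody, no test across libraries was possible and no p-value was computed across genes. The permutation p-values concern only where these peaks lie under circular shifts. The steps were tested on simulated data. With 0, 20 and 50% of 31156 simulated peaks planted in H3K4me3 peaks, 1.25, 21.0 and 50.6% overlapped. Of unchanged lists of 25 genes, drawn among 20000 genes without matching on H3K4me3, 3.3% lay in the upper 2.5% of random lists. Of lists with members at 95%, 99.9% did. That share is not the power of the matched comparison, since 95.4% of the marked genes in these data had ETV5.

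The 18 gene lists, the alternatives listed in this paragraph and the rule for named genes were fixed before the data were examined. Further alternatives, and a second endothelial and a second leukocyte list, were added later. Named are the 5 highest-fold ETV5 peaks inside and outside H3K4me3, the 3 widest and the 3 highest-fold H3K4me3 peaks, the 10 genes nearest to the highest-fold ETV5 peaks, Etv5, the up to 4 members of each list with the highest fold, and in the AT2, AT1, MAPK feedback, lipid and transcription factor lists up to 4 members without ETV5. Some items that this rule names are not reported here. Alternatives covered stricter thresholds, other overlap rules, uniform placement, windows of 1, 5 and 20 kb, unmatched lists, all annotated genes and bins of 100 kb. Peaks on unplaced scaffolds and mitochondrial DNA were left out of the comparisons. In the macrophage and leukocyte list 20 of 22 written symbols were in the gene table. The complex I list holds every gene with a symbol starting with Nduf, and the proteasome list every one starting with Psma, Psmb, Psmc or Psmd and a digit. Members such as Ndufaf1 and Psmc3ip came in by prefix, so not every member need be a subunit of the complex.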

Results

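Chromatin from alveolar type II (AT2) cells of C57BL/6 mice, the surfactant-producing epithelial cells of the gas-exchange region of the lung, was immunoprecipitated with an antibody against ETV5 and with an antibody against histone H3 trimethylated at lysine 4 (H3K4me3), a mark of active promoters. ETV5 is an ETS-family transcription factor that acts downstream of FGF and ERK signalling. The series holds 3 samples, 1 ETV5 library, 1 H3K4me3 library and 1 input library, and 2 peak lists were analysed, 1 per antibody. After the caller's filtering, 5715049 ETV5 tags and 34907608 H3K4me3 tags remained. With 1 library per antibody there is no replicate check of any value below. Intervals are exact 95% Clopper-Pearson or Poisson intervals and cover counting error only. The fold enrichment, p-value and q-value of each peak are the authors' own and were not computed again. They were used here to describe and rank peaks, to set stricter thresholds, and to match and compare gene lists.

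ETV5 gave 31165 peaks, about 2.06 for each of the 15134 H3K4me3 peaks, and most of them were narrow and of low fold. The highest-fold ETV5 peak lay at one end of Bcl6, which encodes a transcriptional repressor (chromosome 16, 23988366 to 23989219, GRCm38). It reached a fold enrichment of 165 and a pileup of 324 fragments (interval 290 to 361), with its summit 55 bp from the gene boundary and inside the gene. Other peaks among the strongest lay at Cadm2, a cell adhesion gene (chromosome 16, 67619708 to 67621701, fold 156), and at Tut7, an RNA uridylyltransferase (chromosome 13, 59822386 to 59823653, fold 151). Bzw1, Git2 with Ankrd13a, Dohh, Noct and Rnf44 were also among the 10 loci of highest fold, from 151 at Bzw1 to 145 at Rnf44. Each of these named peaks overlapped an H3K4me3 peak, with summits 41 to 325 bp from a boundary.

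Over the ETV5 peaks on assembled chromosomes the median fold was 6.60 (quartiles 4.91 and 11.9), the median pileup 13 fragments (9 and 25) and the median width 402 bp (253 and 729), and the peaks covered 17.3 Mb. In the whole list a fold of at least 10 was reached by 9571 peaks (30.7%) and a −log10 q of at least 10 by 13443 peaks, so that the size of the list depends on the threshold by more than 2 times. H3K4me3 peaks on assembled chromosomes were wider, with a median of 1220 bp (768 and 1711) and a median fold of 26.6 (9.70 and 40.6), and covered 20.4 Mb. The highest-fold H3K4me3 peaks lay in Atxn2l (chromosome 7, 126501578 to 126504121, fold 74.7), at Ppp2ca (chromosome 11, 52098592 to 52100271, fold 72.1) and in Ywhaz (chromosome 15, 36791425 to 36794870, fold 72.1), and each held at least 1 ETV5 peak. Folds of the 2 lists are not on a common scale, since the ETV5 library had fewer tags and was called against another input library. The 1 added to pileup and background also lowers fold more at the ETV5 background (median 1.04 at autosomal peaks) than at that of H3K4me3 (5.38).

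The comparison of both lists asked how far ETV5 occupied regions that carry the mark of active promoters. ETV5 peaks were concentrated there: 15229 of 31156 peaks on assembled chromosomes (48.9%, interval 48.3 to 49.4) overlapped an H3K4me3 peak, against a mean of 1.21% and a maximum of 1.51% over 1000 circular shifts of the ETV5 list. Conversely, 12742 of 15129 H3K4me3 peaks (84.2%, 83.6 to 84.8) held an ETV5 peak, against a mean of 2.20% and a maximum of 2.71%. No shift reached either share (one-sided permutation p = 0.001, the smallest that 1000 shifts can give), a test of the placement of these lists and not of replicate libraries. Of the 15927 ETV5 peaks outside H3K4me3, 4305 (27.0%, 26.3 to 27.7) lay within 5 kb of an H3K4me3 peak, against 6.75% after shifting. The shifted share also counts peaks that landed inside H3K4me3, which the observed share leaves out by definition.

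The share depended on peak strength. Among the decile of ETV5 peaks with the highest fold, which holds Bcl6, Cadm2 and Tut7, 94.7% (93.9 to 95.5) overlapped H3K4me3, and in the weakest decile 15.9% (14.7 to 17.3) did. With only the ETV5 peaks of −log10 q of at least 10 the share was 81.1%, and with only those of fold of at least 10 it was 87.5%. ETV5 peaks inside H3K4me3 had a median fold of 11.1 (quartiles 6.88 and 18.8) and a median width of 682 bp, and those outside had a median fold of 5.30 (4.48 and 6.52) and a median width of 280 bp, a ratio of 2.09 in fold. The H3K4me3 peaks that held an ETV5 peak had a median fold of 31.2 and a median width of 1336 bp. Those without one had a median fold of 5.80 and a median width of 559 bp, 5.38 times lower in fold.

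**Figure D1:**
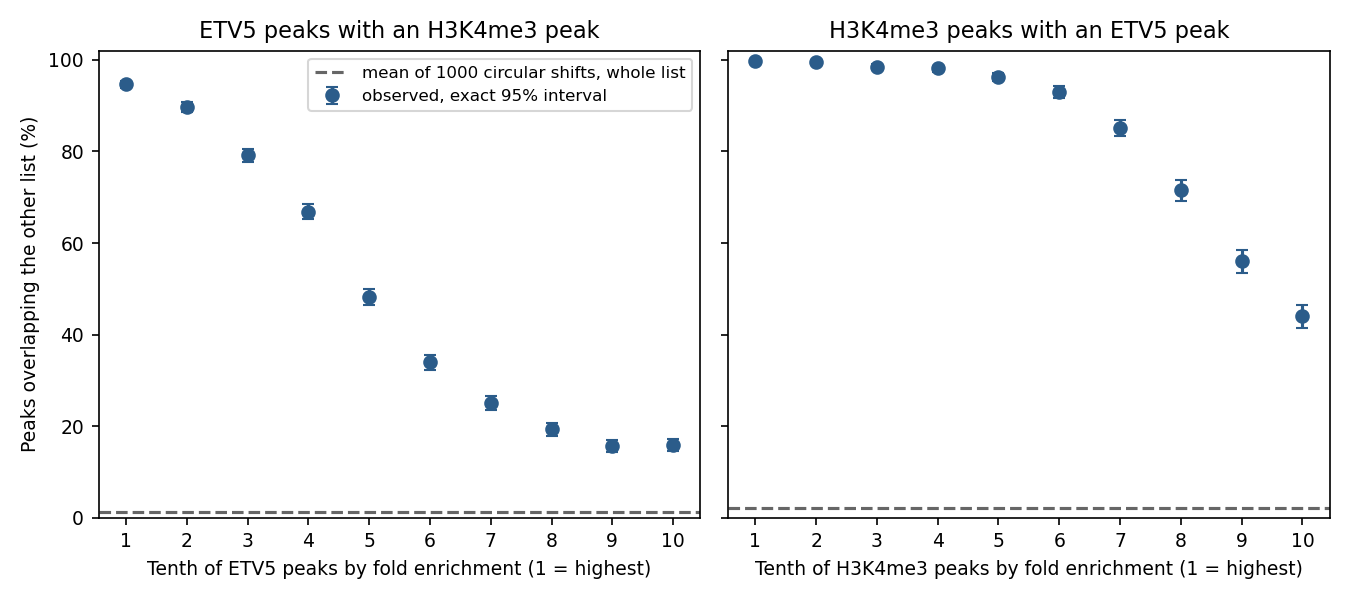
Share of peaks (%) that overlap the other list, for each decile of the ETV5 list (left) and of the H3K4me3 list (right) ranked by the authors' fold enrichment, decile 1 being the highest; points are observed shares with exact 95% intervals, and the dashed line is the mean of 1000 circular shifts over the whole list. The share falls from 94.7% to 15.9% over the ETV5 deciles and from 99.9% to 44.0% over the H3K4me3 deciles, and stays above the shifted level in each.

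In the decile of highest fold, few ETV5 peaks lay outside H3K4me3. Of the 5 highest-fold peaks outside it, all but the fifth lay inside a gene. The highest was in Ttc13 (chromosome 8, 124691364 to 124692893, fold 112, pileup 250, interval 220 to 283), 27538 bp from the nearest H3K4me3 peak. Others lay in Tnrc6a, which encodes a component of microRNA silencing (chromosome 7, 123097552 to 123098432, fold 89.8), in Nme7 (chromosome 1, 164413270 to 164414172, fold 81.8) and in Mtcl1 (chromosome 17, 66357530 to 66358969, fold 77.7), each more than 20 kb from a boundary and from an H3K4me3 peak. The fifth was beside Gart, a purine synthesis gene (chromosome 16, 91620671 to 91622165, fold 67.4), 188 bp from the gene boundary and 1483 bp from H3K4me3. Exons and introns were not told apart, because the gene table used here gives only the ends of each gene.

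Relative to protein-coding genes, 12728 ETV5 summits (40.9%, 40.3 to 41.4) lay within 1 kb of a gene boundary, against a shifted mean of 3.26% and a maximum of 3.89% (one-sided permutation p = 0.001). A further 12403 (39.8%, 39.3 to 40.4) lay inside a gene and farther than 1 kb from every boundary, against a shifted mean of 39.6% (one-sided permutation p = 0.41). Another 6025 (19.3%) lay between genes, against 57.2%. These shares are of all summits, so the share inside genes is lowered by the many summits at boundaries. Away from boundaries more ETV5 summits lay inside genes than between them, whereas after shifting more lay between genes. Inside H3K4me3 peaks the boundary share was 69.2% and the share inside genes 22.7%. Outside H3K4me3 these were 13.8% and 56.1%. Both ends of each gene were counted, since strand was not used here, and start sites inside the annotated extent of a gene count as inside it.

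ETV5 lay within 5 kb of a boundary of 13241 of 21883 protein-coding genes (60.5%). Of the 11407 genes with H3K4me3 within 1 kb of a boundary, 10886 (95.4%, 95.03 to 95.81) had an ETV5 peak, with a median highest fold of 15.8. Of the 10476 genes without it, 2355 (22.5%, 21.7 to 23.3) had one, with a median of 7.05. Each of the 18 gene lists was therefore set against 10000 random lists with as many H3K4me3-marked genes, and percentiles describe these lists only.

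Among 25 AT2 markers, 22 carried H3K4me3 and 20 had an ETV5 peak, with 21.7 in random lists (10.2nd percentile). Against lists matched also on quintiles of H3K4me3 fold, an alternative added after the data were seen, the count lay at the 1.505th percentile (22.3 in random lists). With each peak given only to the gene of the nearest boundary, also added after, 20 had ETV5 against 19.6 in random lists (56.3rd percentile). A window of 20 kb gave the 90.2nd percentile and no matching the 97.7th. A window of 1 kb gave the 7.665th and −log10 q of at least 10 the 7.045th. Sftpb, which encodes surfactant protein B, had the strongest, at fold 117 (pileup 289, interval 257 to 324; chromosome 6, 72303479 to 72306139), overlapping one edge of a 7535-bp H3K4me3 peak. Nkx2-1, the transcription factor of lung epithelial identity, had fold 32.9, the mucin gene Muc1 fold 30.4 and fatty acid synthase Fasn fold 26.5. Sftpc, which encodes surfactant protein C, had fold 15.6 with Bmp1 as the gene of the nearest boundary. Dlk1, Il33, Lamp3, Lyz1 and Lyz2 had no peak within 5 kb, although Lamp3, Lyz2 and Il33 carried wide H3K4me3 peaks of 5672, 4282 and 3832 bp. Sftpc and Lyz2 were named after their values were seen. Etv5 itself had a peak of fold 21.8 (pileup 48, 35.4 to 63.6; chromosome 16, 22379232 to 22380155) 1741 bp outside one end of the gene, and a peak of fold 16.3 (22438247 to 22440180) at the other end, where a 6698-bp H3K4me3 peak lay.

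The 30 MAPK feedback and ETS-response genes, which include inhibitors of RAS and ERK signalling, had ETV5 at 29 members, all but Spry3 (27.9 in random lists, 80.0th percentile), with a median fold of 26.5. Spred2 had fold 105, Spred1 fold 99.2, the RAS GTPase-activating gene Nf1 fold 67.9, and the immediate early gene Ier2 fold 46.3. Of 28 genes from the FGF and EGF receptors to ERK, 27 had ETV5 (26.7 in random lists, 54.9th percentile), the highest at Nras and Rps6ka3 with fold 67.3 each, then Frs2 with 66.1 and Erbb2 with 39.1. Of 32 surfactant and lipid synthesis genes 29 had ETV5, against 25.4 in random lists (98.9th percentile). They included Pcyt1a, the rate-limiting enzyme of phosphatidylcholine synthesis, at fold 69.0, the triglyceride enzyme Dgat2 at 54.1, the sterol response regulator Insig2 at 49.0 and ATP citrate lyase Acly at 29.7, and not Abcg1, Lpin1 or Pcyt1b. The lipid list left the upper 2.5% with a window of 1 kb (23 members, 38.7th percentile), with a window of 20 kb (91.6th) and at −log10 q of at least 10 (86.5th). Of its 4 unmarked members with ETV5, Insig2, Srebf1 and Elovl6 had the highest ETV5 peak in an H3K4me3 peak. Those summits lay 4767, 3629 and 1675 bp from a boundary, so matching on H3K4me3 within 1 kb did not cover them.

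Of 29 lung epithelial transcription factors 26 had ETV5 (24.0 in random lists, 91.5th percentile), among them Yap1 at fold 107, Foxp2 at 52.9, Nkx2-1 at 32.9 and the H3K4 demethylase Kdm5b at 28.8. Elf5, Hopx and Trp63 had none. All 76 cytosolic ribosomal protein genes had ETV5 (71.8 in random lists, 99.7th percentile), with a median fold of 22.8 and the highest at Rpl32 (92.1), Rpl8 (87.2), Rps3a1 (56.8) and Rps14 (51.6). Random lists matched also on quintiles of H3K4me3 fold, an alternative added after the data were seen, put that count at the 95.6th percentile. With each peak given only to the gene of the nearest boundary, also added after, 68 of the 76 had ETV5 (65.2 in random lists, 82.05th percentile). ETV5 was near 46 of 49 complex I genes (91.1st percentile; Ndufb1 108, Ndufa13 49.1, Ndufv2 47.1), 37 of 40 proteasome genes (73.8th; Psmd12 90.6, Psma7 58.2, Psmd13 32.5, Psmc4 30.6), all 24 cell cycle genes (96.3rd; Mcm7 81.9, Pcna 76.5, Mcm4 68.3, Cdk2 46.1) and 16 of 18 antigen presentation genes (31.0th; Tapbp 68.9, H2-DMa 36.8, Irf1 25.5), with the fold of the highest peak after each name. Several of these peaks had their nearest boundary in a neighbouring gene, such as Cpsf2 for Ndufb1, Ap4m1 for Mcm7, Rgl2 for Tapbp, Commd5 for Rpl8 and Ss18l1 for Psma7. The best peak was nearest to the member itself in 27 of the 46 complex I genes and in 28 of the 29 MAPK feedback genes. With peaks given only to the nearest gene, 34 of the 49 complex I genes had ETV5, fewer than the 39.7 in random lists (1.33rd percentile).

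Among markers of other lung cell types, H3K4me3 marked 8 of 15 ciliated, 4 of 15 airway secretory, 2 of 12 basal, 1 of 15 mesenchymal and 4 of 20 leukocyte genes. AT1 markers, of the neighbouring thin alveolar cell type, had H3K4me3 at 13 of 20 members and ETV5 at 13 (14.0 in random lists, 23.4th percentile), with Col4a3 at fold 96.6 (nearest boundary in Mff), Ager at 20.9 (nearest boundary in Agpat1), Vegfa at 16.0 and Emp2 at 15.2, and without Cldn18, Clic5, Hopx and Igfbp2 among others. ETV5 lay near 11 of 15 ciliated cell markers (90.7th percentile; Ccno 34.0, Cfap126 27.3, Ccdc78 14.8, Foxj1 11.4), 7 of 15 airway secretory markers (69.8th; Cbr2 10.6, Bpifb1 8.39, Cyp2f2 7.33, Scgb1a1 5.30), 4 of 12 basal markers (47.5th; Itgb4 56.5, Itga6 13.4, Ngfr 7.57, Aqp3 6.42), 4 of 15 mesenchymal markers (49.6th; Pdgfra 6.87, Col1a1 6.41, Pdgfrb 6.01, Vim 3.83) and 5 of 20 macrophage and leukocyte markers (8.19th; Coro1a 24.7, Cd68 11.1, Spi1 7.29, Cd14 6.74). Endothelial markers stood apart, with ETV5 near 10 of 15 members against 4.83 in random lists (99.8th percentile), although only 2 carried H3K4me3. Their folds were low, with a median of 5.15, and the highest were at Esam (10.4), Sox17 (6.37), Ramp2 (6.23) and Egfl7 (5.67). Only 1 of the 15 kept a peak when −log10 q of at least 10 was required, and the list also left the upper 2.5% with a window of 1 kb (92.9th percentile), with a window of 20 kb (96.3rd) and without matching (68.2nd). Of the peaks named for these cell types, those at Itgb4 (Galk1), Coro1a (Bola2), Cd68 (Mpdu1), Ccdc78 (Antkmt), Cbr2 (Dcxr), Bpifb1 (Bpifb5) and Pdgfrb (Gm52351) had their nearest boundary in the gene in parentheses. As a negative control, 7 of 1110 olfactory receptor genes had ETV5 (0.631%, 0.254 to 1.30, with 249.6 in random lists), the highest at Olfr986 with fold 31.2 (nearest boundary in Zfp202), then Olfr159 (8.46), Olfr288 (7.41) and Olfr1393 (5.63). These 1110 unmarked genes were also in the pool for random lists, which lowers the random mean of lists with many unmarked members, such as the endothelial list.

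**Figure D2:**
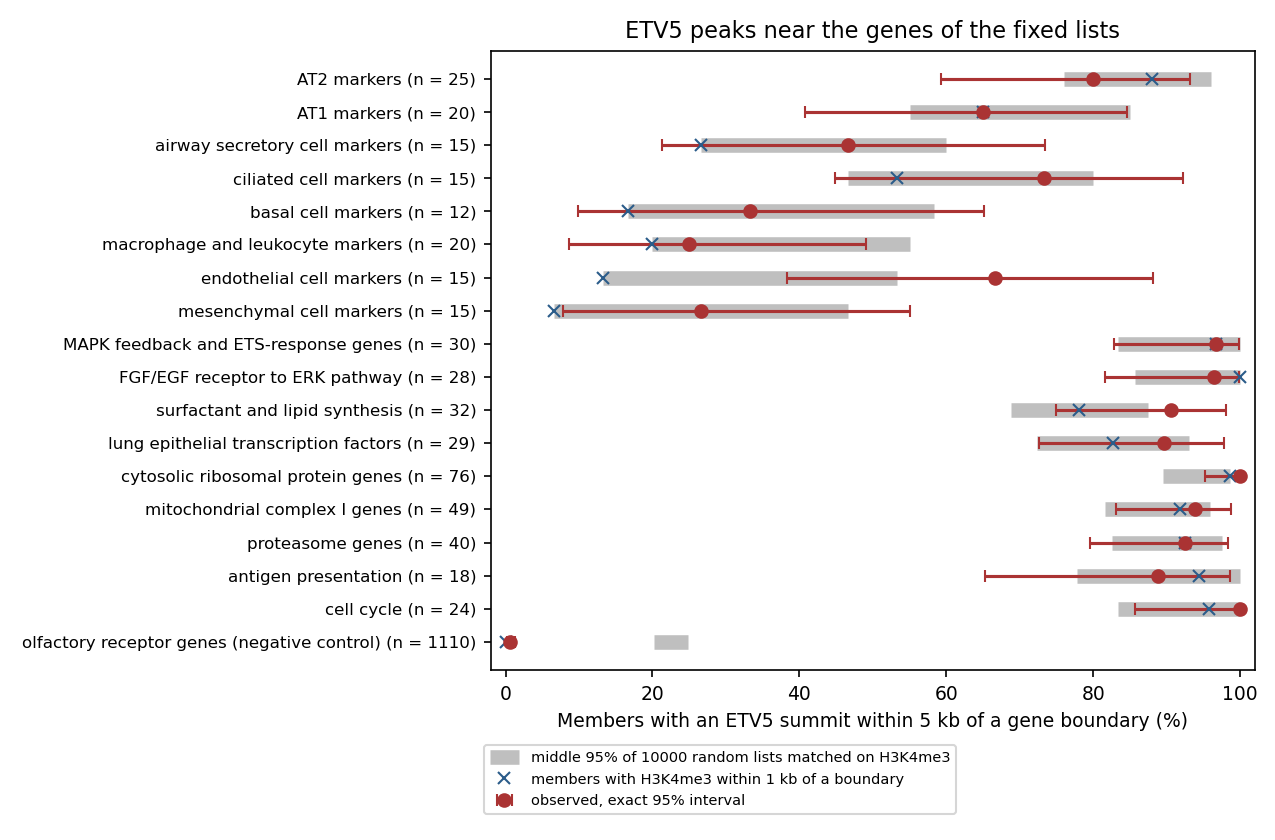
Percent of members of each list with an ETV5 summit within 5 kb of a gene boundary (red points with exact 95% intervals), the middle 95% of 10000 random lists matched on H3K4me3 status (grey), and the percent of members with H3K4me3 within 1 kb of a boundary (blue crosses). The endothelial, lipid synthesis and ribosomal protein lists lie in the upper 2.5% of random lists, and the olfactory receptor genes lie at 0.631%. In the MAPK feedback, FGF and EGF receptor, antigen presentation and cell cycle lists the grey bar reaches the whole list, so no count could exceed it.

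**Figure D3:**
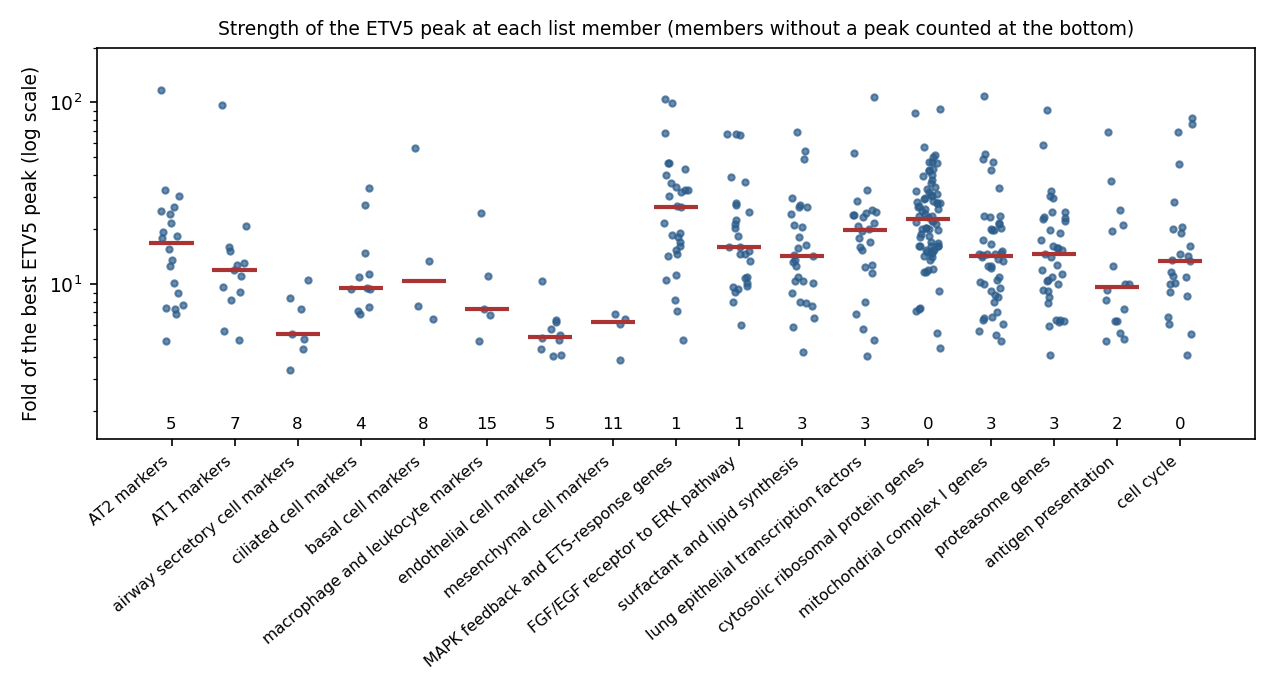
Fold enrichment (log scale) of the highest ETV5 peak within 5 kb of each list member, 1 point per member with a peak, the red line being the median of those members; the number of members without a peak is printed at the bottom. The MAPK feedback genes have a median of 26.5 and the ribosomal protein genes 22.8, and the endothelial markers have 5.15.

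The width of the H3K4me3 peaks was also compared with ETV5. The widest 3 lay over Irx5 (chromosome 8, 92351857 to 92367174, 15318 bp, with 5 ETV5 peaks), over Nkx2-1 (chromosome 12, 56525502 to 56538435, 12934 bp, with 2) and over Slc34a2, the phosphate transporter of AT2 cells (chromosome 5, 53047115 to 53059184, 12070 bp, with 1). Among the decile of H3K4me3 peaks with the largest width, 98.1% (97.3 to 98.7) held an ETV5 peak, against a maximum of 5.75% under shifting. In the narrowest decile the share was 45.3% (42.7 to 47.8), against a maximum of 2.25%. An H3K4me3 peak held 2 or more ETV5 peaks in 2398 cases.

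**Figure D4:**
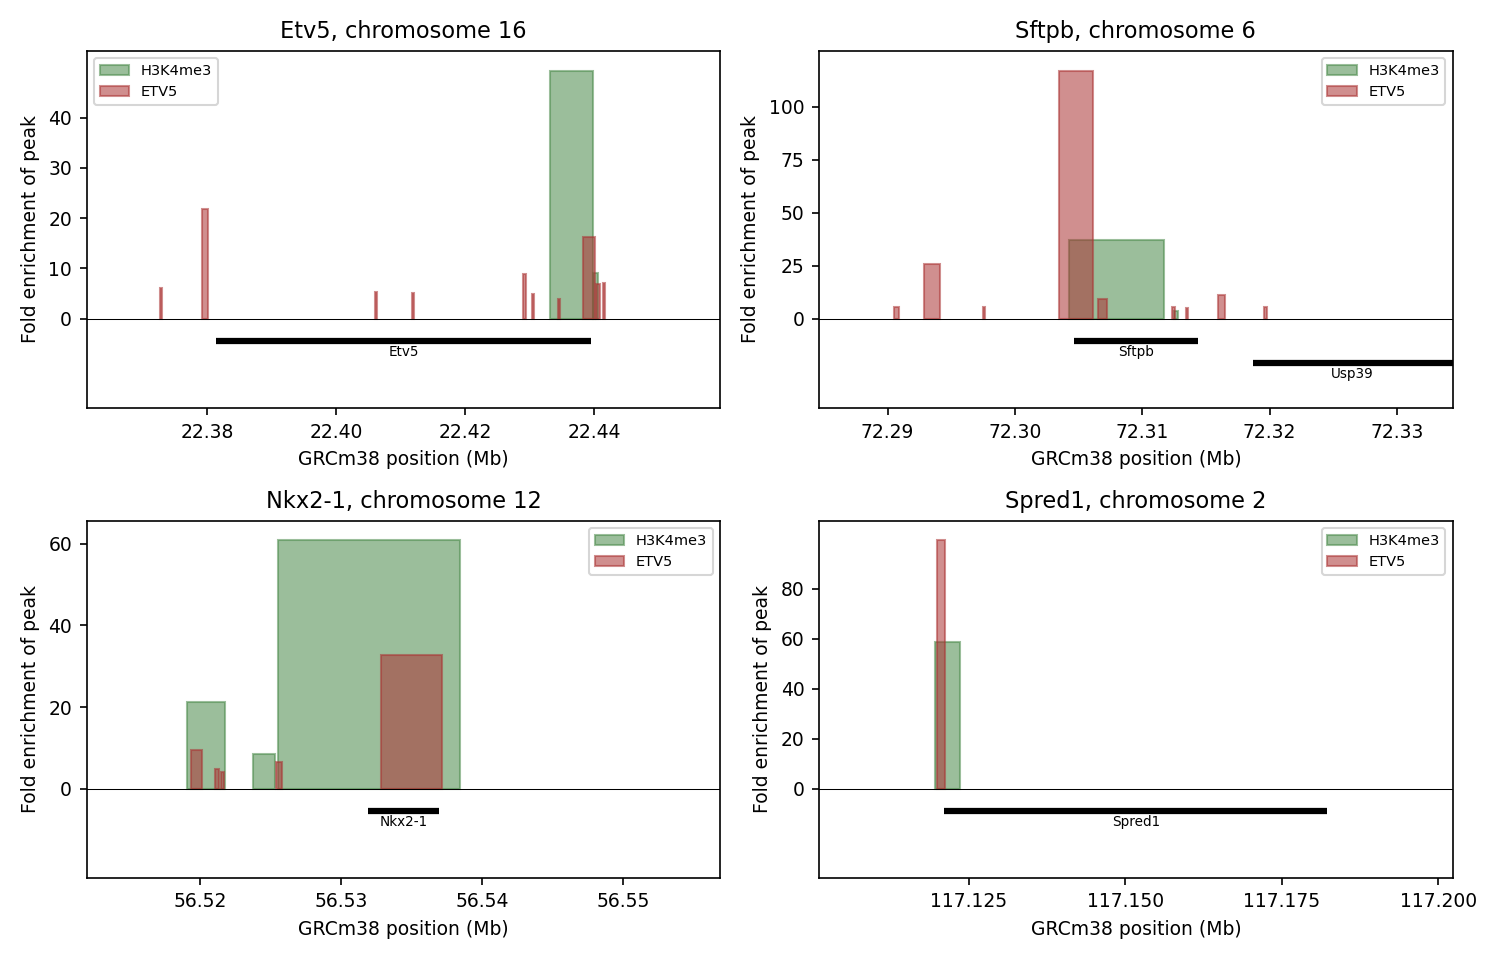
Peaks of ETV5 (red) and H3K4me3 (green) as boxes from start to end in Mb (GRCm38), with height the authors' fold enrichment of the peak, at Etv5, Sftpb, Nkx2-1 and Spred1, and gene extents as black bars. The highest ETV5 peak has fold 117 at Sftpb and 99.2 at Spred1, each toward an edge of the H3K4me3 peak.

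Along the chromosomes both lists followed each other, with a Spearman correlation of 0.937 and a Pearson correlation of 0.912 between peak numbers over 2653 bins of 1 Mb, which are not independent replicates. Chromosome 11 had the most ETV5 peaks per Mb (24.0), and chromosome X had 3.18, fewer than any autosome. The X chromosome also differed in the balance of the lists. It had 522 ETV5 and 487 H3K4me3 peaks, a ratio of 1.07, against 30627 and 14635 on the autosomes, a ratio of 2.09. On X, 71.5% (67.2 to 75.4) of H3K4me3 peaks held an ETV5 peak, and on the autosomes 84.7% (84.1 to 85.3). The autosome with the lowest share was chromosome 3, with 78.4% (75.3 to 81.3). On Y each list had 7 peaks.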

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

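Chosen after the result was seen were the test of endothelial cells in the preparation, the look at unmarked genes of the first lists, and the check of the H3K4me3 background on X. The design holds a single group of animals, so no comparison between animals bears on the 3 patterns weighed here.

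Signal appeared outside the assembled chromosomes: 9 ETV5 peaks lay on unplaced scaffolds or mitochondrial DNA, the highest with fold 85.3, and the mitochondrial peak had fold 1.597. The H3K4me3 list had 5 such peaks, all on unplaced scaffolds, the highest with fold 29.1.

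ETV5 peaks were gathered in H3K4me3 peaks such as those at Sftpb, Spred1 and Bcl6. Recovery that follows the amount of H3K4me3, as open promoter chromatin could give with any antibody, stays open. Over 12742 H3K4me3 peaks with an ETV5 peak, the highest ETV5 fold rose with H3K4me3 fold with a Spearman rho of 0.478, between the bounds set before. A control antibody in these cells would be needed to decide it, and the ETV5 median went from 7.57 in the lowest H3K4me3 decile to 21.0 in the highest.

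ETV5 lay near 8 of 13 endothelial markers without H3K4me3, such as Cdh5 (fold 4.94) and Pecam1 (fold 4.41), against 2.93 in random lists of unmarked genes (99.87th percentile). The unmarked genes drawn from include the 1110 olfactory receptor genes, only 7 of them with ETV5, which lowers such random means. By how much was not measured. A second endothelial list of 30 other genes had 12 with ETV5 (8.94 in random lists) and lay at percentile 90.77, between the bounds set before, so chance in a short list is not excluded. A second leukocyte list of 30 genes had 15 with ETV5 (11.1 in random lists) and lay higher, at percentile 95.9. Unmarked genes of that leukocyte list had ETV5 in 37.50% of cases, within the interval of the unmarked second-list endothelial genes (33.3%, 16.5 to 54.0). This met the bound set before for equal hits on unmarked genes of other cell types. In the first lists it was 2 of 16 (12.5%) against 8 of 13 (61.5%, 31.6 to 86.1). That contrast includes the count that prompted the test, so it is no independent check, and equal hits stay open. Endothelial cells in the preparation also stay open: the 9 unmarked second-list genes with ETV5 had a median fold of 6.775 (order-statistic interval 5.51 to 7.85), not told apart from 7.05 over all unmarked genes with a peak. The labels name no sort that would remove such cells, and at −log10 q of at least 10 only 1 first-list gene kept a peak.

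The X chromosome had fewer ETV5 peaks for each H3K4me3 peak. Weaker H3K4me3 peaks on X (median fold 18.3 against 27.2) are argued against as the whole cause, since the X share lay −9.615 percentage points from the autosomal share in the same deciles of H3K4me3 fold (71.5%, 67.2 to 75.4, against 81.1%). A lower copy number of X, as in male animals, could contribute. The background implied by pileup and fold at ETV5 peaks was 0.675 on X and 1.04 on autosomes, a ratio of 0.650, below the bound set before, from an input other than the one in the labels. For H3K4me3 it was 5.38 on both, the caller's genome-wide minimum, the value at 90.3% of X and 57.0% of autosomal peaks, so the X median could not be lower. For ETV5 the genome-wide minimum was 0.620, the value at 32.0% of X and 4.40% of autosomal peaks. Called ETV5 peaks had a median pileup of 13 on X and on autosomes, and a median fold of 7.64 on X against 6.57. The sex of the animals is not given in the labels, and each list had 7 peaks on Y. How far copy number accounts for the difference was not measured.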

How the results depend on the processing

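Added after the data were seen were the alternatives of shifts of any size, the weakest decile of ETV5 peaks, no sex chromosomes, matching on quintiles of H3K4me3 fold, peaks given to the nearest gene only, and the median fold per list. Among values of the main comparisons under an alternative, 37 stayed on their side of the threshold or within 1.5 times, and 6 moved. Some of the 37 could hardly move. Keeping only assembled chromosomes left 31156 and 15129 peaks, and merging overlapping ETV5 peaks left all 31165. Other placement models changed only the chance share and not the observed one. For the gene lists the tally counts how many lay in the upper 2.5% and not which: with a window of 1 kb these were the ribosomal, complex I and cell cycle lists. The ETV5 list shrank to 13443 peaks at −log10 q of at least 10 and to 9571 at fold of at least 10, by construction. The share of ETV5 peaks in H3K4me3 ran from 15.9% in the weakest decile to 87.5% at fold of at least 10. It stayed above each of the 100 placements run per setting, also with shifts of any size (maximum 3.43%). With −log10 q as the measure, the ratio of ETV5 strength inside over outside H3K4me3 was 3.86 and that of H3K4me3 strength with over without ETV5 was 14.6, on a scale that also grows with pileup. Without matching, 10 lists lay in the upper 2.5% of random lists instead of 3, since most lists hold many marked genes, and at −log10 q of at least 10 only 1 list did, the ribosomal protein genes. The endothelial list fell to 1 member at that threshold (4.42nd percentile), below its random mean, and the lipid list to 23 members with a window of 1 kb, also below; the cause was not tested in either. Without matching, the AT2 list (20 members, 97.7th percentile) and the antigen presentation list (16, 99.5th) went from below to above chance, and the mesenchymal list (4, 0.34th) from near 50 to the lower 2.5%, as it did at −log10 q of at least 10 (0 members, 1.63rd). Complex I genes fell to 34 (1.33rd) with peaks given to the nearest gene only, where the best peak was nearest to the member itself in 27 of 46. The unmatched values of the AT2, antigen presentation and mesenchymal lists follow from their marked members (22 of 25, 17 of 18 and 1 of 15). Unmatched random lists hold marked genes at the rate of all genes, and 95.4% of marked against 22.5% of unmarked genes had ETV5. The cause was not tested for the mesenchymal value at −log10 q of at least 10 or for the complex I value. Of the other values for single lists, 80 stayed between or beyond the same thresholds, and 20 of these crossed the 50th percentile, as the AT2 list did with a window of 20 kb (24 members, 90.2nd). Another 14 passed a threshold newly, and 7 no longer passed it, all in the endothelial, lipid and ribosomal lists. The motif alternatives were not run, as no genome sequence was used here. No paired analysis was possible because each antibody has 1 library. With 5715049 ETV5 tags, genes without a called peak may still carry ETV5 below the depth of this library, where the smallest called pileup was 5 fragments, and the 9571 peaks of fold of at least 10 are the part least affected.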

Other observations

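The tests of list medians, of H3K4me3 width by list and of peaks in the widest domains were chosen after the data were seen. Lists differed in the strength of ETV5 as well as in its presence. The median of the highest ETV5 fold per member, with 0 where there was no peak, was 24.2 in the MAPK feedback genes against 14.9 in matched random lists (99.8th percentile). It was 22.8 in the ribosomal protein genes against 15.03 (100th percentile) and 18.0 in the lung epithelial transcription factors against 13.0 (97.3rd percentile). In the AT2 markers it was 12.6 against 13.7 (37.2nd percentile). In the antigen presentation genes it was 8.73 against 14.7, at the 0.86th percentile, although 17 of 18 carried H3K4me3, and H2-Aa, an MHC class II gene with H3K4me3 of fold 31.7, had no ETV5 peak. Random lists for these medians were matched on the presence of H3K4me3 and not on its fold or width. Since the highest ETV5 fold rose with H3K4me3 fold (Spearman rho 0.478), a preference beyond the strength of the mark was not tested.

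H3K4me3 peaks were wide over AT2 markers and narrower over ribosomal protein, complex I and proteasome genes. Of the 25 AT2 markers 19 carried an H3K4me3 peak from the widest decile (2308 bp or more), with 2.93 in random lists (100th percentile) and a median width of 4728 bp over marked members, and 12 one from the widest 1% (4306 bp or more). The widest decile also marked 19 lung epithelial transcription factors, 18 MAPK feedback genes and 16 lipid synthesis genes, each at the 100th percentile, among them Foxa1 (9721 bp), Gata6 (8215 bp), Spry2 (6758 bp) and Scd1 (5690 bp). It marked only 3 of the 76 ribosomal protein genes (0.37th percentile), 1 complex I gene and 0 proteasome genes. The median width over marked ribosomal protein genes was 1532 bp. Of the 152 H3K4me3 peaks in the widest 1%, 148 held an ETV5 peak, with a median of 2. The 4 without one lay nearest to Lamp3 (5672 bp), Nedd4l (4416 bp), Hc (6127 bp) and Bmp5 (4613 bp), and Hc and Lamp3 are AT2 markers. The summit of the domain nearest to Hc lay 7397 bp from the gene boundary. Hc itself counted as unmarked and had an ETV5 peak of fold 8.90 within 5 kb. The nearest ETV5 peak was 1422 bp from the Lamp3 domain and 113063 bp from the Bmp5 domain.

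One hypothesis was that the strongest ETV5 peaks lie more often than others at promoters shared by neighbouring genes, as at Git2 with Ankrd13a. Among ETV5 peaks in H3K4me3, 18.9% (16.9 to 20.9) of the 1522 in the highest-fold decile had boundaries of 2 or more genes within 1 kb of the summit, against 10.0% (9.52 to 10.5) of the other 13707, a difference of 8.840 percentage points. Among peaks with at least 1 such gene the shares were 23.4% (21.0 to 25.8) and 14.8% (14.0 to 15.5). The share was higher in the strongest decile, but most of its peaks had no second gene so near, and boundaries that are ends rather than starts of genes were counted too.

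A further hypothesis was that ETV5 sits upstream of the H3K4me3 summit at the same promoter. At 7515 boundaries with both summits within 1 kb, the ETV5 summit lay inside the gene in 74.1% (73.1 to 75.1) and the H3K4me3 summit in 93.0% (92.4 to 93.6), a difference of −18.882 percentage points. The median position was 109 bp into the gene for ETV5 and 267 bp for H3K4me3, and ETV5 lay on the outer side of the H3K4me3 summit in 74.1% of boundaries. This may be the position of ETV5 near the start site with the marked nucleosome inside the gene, but starts and ends of genes were not told apart.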
